A study of Mus musculus with 16 samples.

How the data were processed

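RNA was measured in 16 libraries from cultured mouse cardiac fibroblasts, the cells that make most of the heart's extracellular matrix. Per the labels' protocols, cells at passage 2 were starved of serum for 24 h and given an adenovirus carrying either Cre recombinase, which removes exon 2 of a floxed Has2 gene, or green fluorescent protein (GFP) as the control. After 5 h they received fresh medium, and total RNA was isolated after 48 h of stimulation. The treatment protocol describes the cells as coming from Has2-floxed mice, whereas the genotype field of the labels reads wild type, and the labels do not settle which applies. The protocol names 20 ng/mL of basic fibroblast growth factor and transforming growth factor beta (TGF-beta) in 1 phrase, so whether the cells without TGF-beta received the other factor is not stated. A Has2 overexpression virus named in the protocol was not analysed here. Total RNA was extracted with Trizol, treated with DNase and made into libraries with the NEBNext Ultra II kit, per the labels' protocols.

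The authors deposited 1 table of raw read counts per gene, with 55414 Ensembl gene identifiers and 16 columns. The values are whole numbers, were not normalized, and include no summary lines. Per the submitters' processing notes, FastQC 0.10.1 and HTSeq 0.10.0 were used, with the genome build mm39 (GRCm39). The aligner, the gene annotation and the strand setting are not given in the sources used here, so overlapping, antisense and near-identical genes are uncertain. Gene symbols came from GENCODE M21, an annotation of an earlier build. It matched 52081 identifiers, which held 99.9% of all counts. The exon lengths of Has2 and the GC content and length of transcripts also came from it, and it was not used to count reads.

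Each column was assigned to a sample through its library name. The groups were GFP, Cre, GFP with TGF-beta and Cre with TGF-beta, with 4 libraries in each. Library totals ranged from 17.9 to 48.7 M counts. Genes were kept with filterByExpr of edgeR (minimum count 10, minimum total count 15), which left 15285 genes holding 99.9% of the counts. The 40129 others were not tested. Counts were scaled with TMM factors, which ranged from 0.908 to 1.12. Xist and Ddx3y matched the labelled sex in all 16 libraries. No library pair of a group lay within sampling noise (chi-square per gene from 6.58 to 214), so none was treated as a duplicate.

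The test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with robust estimation, 1 mean per group, no replicate block and all 16 libraries in one fit. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) are the fold change divided by the square root of F, and fitted fold changes used a prior count of 0.125. Comparisons were Cre against GFP without TGF-beta, the same with TGF-beta, TGF-beta against none in GFP cells, the same in Cre cells, and the difference between these last responses.

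Libraries with the same replicate number came from the same preparation of cells, since their library names share a preparation code and sex (preparations 1 and 4 male, 2 and 3 female). Their deviations from the group means correlated in all 24 same-numbered pairs (r from 0.323 to 0.838, median 0.497), against a median of -0.130 and a maximum of 0.292 over the 72 other pairs. In 48 of 48 comparisons the best match carried the library's own number. A fit with the preparation as a block was therefore set beside the unblocked gene counts, list counts and list calls where it changed them. The biological coefficient of variation was 0.254 without the block and 0.123 with it. Whether each preparation came from 1 heart or several is not stated. Without the block, p-values measure the spread between these 4 preparations. With it, they measure how much the differences within preparations vary over the same 4.

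The 24 gene lists, of 13 to 47 genes, and the rule for the genes named were fixed before the data were examined. Named genes were 13 fixed genes of hyaluronan metabolism, matrix and myofibroblasts, whatever their result (1 of them is not reported here), the 6 highest and 6 lowest called genes per comparison with an established symbol, a mean of at least 2 CPM (counts scaled to the library total, per M counts) in the higher group and the same direction in all 4 preparations, and up to 4 members of each list with the smallest adjusted p. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 24 lists and 5 comparisons together. Alternatives were camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way without comparing them with other genes.

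Other alternatives were DESeq2 1.42.0, RLE size factors, no filter and a stricter filter (5 CPM in 4 libraries), only the libraries compared, sex as a covariate, glmTreat against a fold of 1.5, and leaving out each library or preparation in turn. The tests were tried on simulated counts for 15285 genes, built from the fitted means and the blocked dispersions. In them 200 genes were changed between Cre and GFP cells, both with and without TGF-beta. The comparison without TGF-beta was tested. The unblocked test recovered 20.0%, 44.0%, 66.0% and 86.0% of genes changed by 1.5, 2, 3 and 4 fold, with 0 false calls. The blocked test recovered 48.0%, 76.0%, 84.0% and 92.0%, with 8 false calls among 158. In a separate draw of simulated counts, only the interferon list was raised in Cre cells, by 1.5 fold. Camera without the block called that list and 0 of the 23 others. The simulated genes were drawn independently, so this trial cannot show how camera at the preset correlation fares with correlated genes. In the real counts the estimated correlation of the interferon list was 0.66, for Cre against GFP without TGF-beta and without the block.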

Results

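Gene expression was measured by RNA sequencing in mouse cardiac fibroblasts given a Cre or a GFP adenovirus, each with and without TGF-beta, a growth factor that drives fibroblasts towards contractile, matrix-producing myofibroblasts. The Cre virus was used to force deletion of Has2, which encodes a synthase of hyaluronan, the large glycosaminoglycan of the extracellular matrix. The 4 groups held 4 libraries each, 1 from each of 4 cell preparations. Mean depth was 23.5 ± 4.58 M counts (SD, n = 4) in GFP cells, 36.0 ± 11.1 in Cre cells, 26.0 ± 10.5 in GFP cells with TGF-beta and 27.5 ± 3.72 in Cre cells with TGF-beta. The first principal component held 55.3% of the variance and separated the libraries with TGF-beta from those without. The second held 20.3% and set the 4 libraries of preparation 4 apart from the other 12. In preparation 4 the 10 most abundant genes took 6.88% to 7.34% of the counts, and in the others 10.3% to 12.1%.

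**Figure D1:**
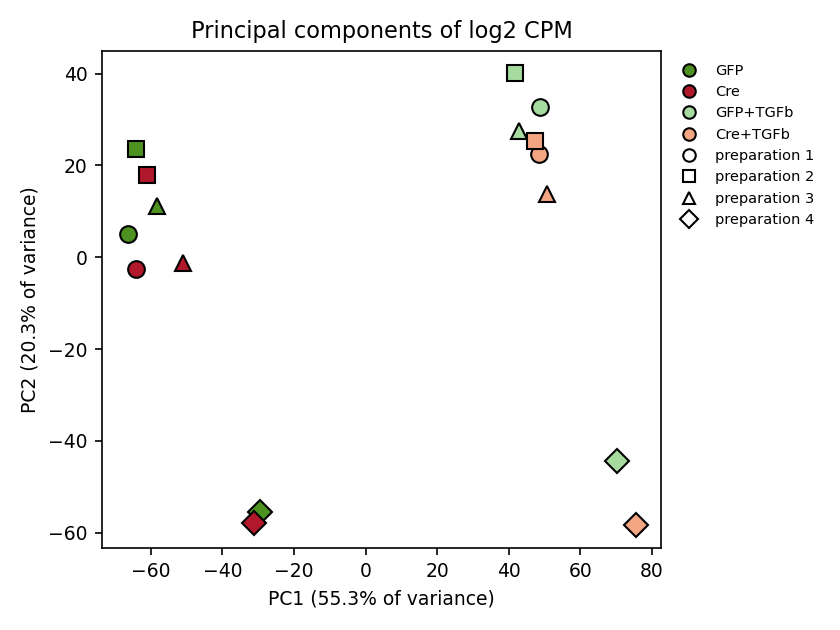
Principal components of log2 CPM over the tested genes, with the first component on the x axis and the second on the y axis, both in arbitrary units; colours mark the 4 groups and symbols the 4 preparations. Libraries with TGF-beta lie to the right on the first component (55.3% of the variance), and preparation 4 lies below the others on the second (20.3%).

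The targeted gene was examined first. Has2 (ENSMUSG00000022367) stood at 18.7 ± 3.27 CPM (SD, n = 4) in GFP cells and 14.7 ± 1.38 in Cre cells. With TGF-beta it stood at 16.8 ± 5.67 CPM in GFP cells and 16.5 ± 6.32 in Cre cells. Raw Has2 counts ranged from 275 to 656 per library. The Cre against GFP difference did not pass edgeR's quasi-likelihood test in either medium. It was -0.35 ± 0.26 (log2 fold change ± SE, adjusted p = 0.9997) without TGF-beta and -0.03 ± 0.26 (adjusted p = 0.9996) with it. Has2 was lower in the Cre library in 4 of 4 preparations without TGF-beta and in 2 of 4 with it. In the fit with the preparation as a block, the Has2 difference without TGF-beta was -0.32 with a 95% interval from -0.645 to 0.0045. With TGF-beta it was -0.04 in that fit, with an interval from -0.36 to 0.29. Averaged over both media in the same fit, the Has2 difference was -0.18 with a 95% interval from -0.41 to 0.05. Counts were summed over the whole gene, so the reads of exon 2 could not be separated from those of exons left in place. Exon 2 makes up 14.8% of the 4237 bases of the Has2 transcript in GENCODE M21. Loss of its reads alone in all cells would give a log2 change of -0.23.

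Has1, the second hyaluronan synthase gene, stood at 1.97 ± 1.73 CPM in GFP cells and 2.46 ± 2.06 in Cre cells (SD, n = 4), a log2 difference of 0.34 ± 0.71 that did not pass the test. By preparation Has1 was at 0.301, 1.12, 2.14 and 4.31 CPM in GFP cells, from as few as 8 counts. In Cre cells it was at 0.549, 1.19, 2.95 and 5.16 CPM, higher in each preparation. With TGF-beta its mean was 2.53 CPM in GFP cells and 2.33 in Cre cells. Has3 had 0 to 10 counts per library and was not tested.

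**Figure D2:**
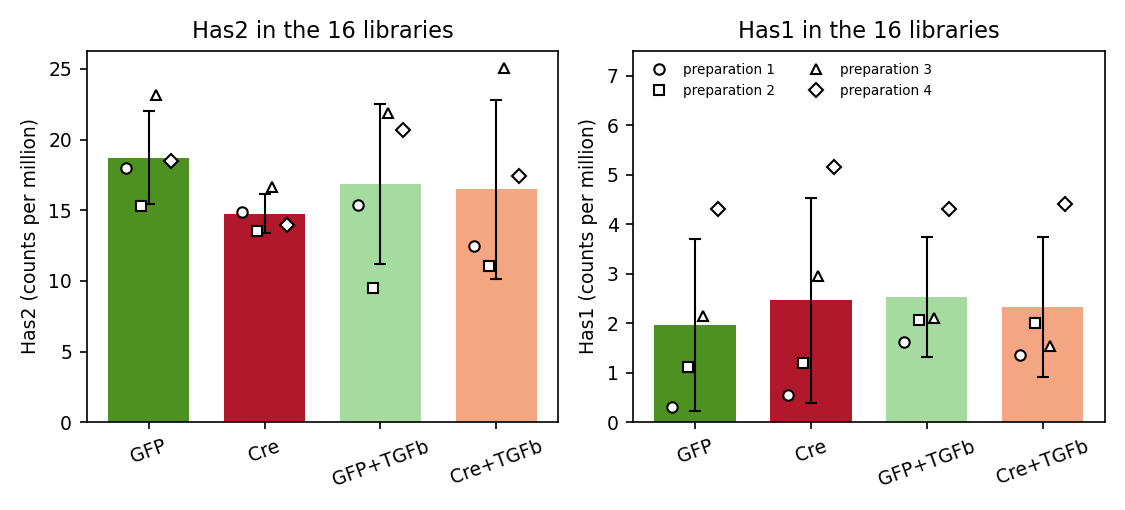
Has2 (left) and Has1 (right) in CPM on the y axis for the 4 groups on the x axis; bars give the mean, error bars the SD (n = 4) and symbols the library of each preparation. Has2 means lie between 14.7 and 18.7 CPM and the preparations overlap between the viruses.

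Cre against GFP cells without TGF-beta asked what differed with the Cre virus in fibroblasts without TGF-beta. The group that stood out was the interferon response, the antiviral genes that type I and type II interferons turn on. Ifit1, an antiviral RNA-binding protein, was at 89.2 ± 27.3 CPM in GFP cells and 186 ± 49.3 in Cre cells (SD, n = 4). The ubiquitin-like Isg15 was at 97.2 ± 35.8 and 221 ± 44.4 CPM, and the guanylate-binding protein Gbp2 at 50.1 ± 4.89 and 91.6 ± 22.8. Over the 42 measured interferon genes the median log2 difference was 0.88, and it was above 0 in each preparation (1.13, 0.72, 1.40 and 0.37). Camera called the list higher (adjusted p = 7.27e-71), but with an estimated correlation the adjusted p was 0.0946. In the fit with the block the adjusted p with an estimated correlation was 0.00792.

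Gene by gene, edgeR's quasi-likelihood test called 0 genes without the block, with 169 genes at an unadjusted p under 0.05 where 764 would be expected by chance, and 882 with the block. DESeq2 called 3, the guanylate-binding proteins Gbp2 and Gbp5 and the ATPase Tor3a, all higher and named after their values were seen. With the preparation as a block, edgeR called 25 genes higher and 1 lower. Among the 42 interferon genes, 0 passed over all genes and 3 adjusted over the list alone without the block. With the block 11 rose and 31 did not pass over all genes, and 41 passed adjusted over the list alone. In that fit Gbp2 rose by 0.84 ± 0.11 (log2 ± SE, adjusted p = 0.0344), Ifit1 by 1.08 ± 0.17 (adjusted p = 0.0344) and the peptide transporter Tap1 by 0.52 ± 0.10 (adjusted p = 0.0482), each higher in 4 of 4 preparations. Other interferon genes called with the block included Oas1a, Cmpk2, Igtp and the chemokine Cxcl10, which rose by 1.59 ± 0.27. The genes named from this fit were chosen after their values were seen. The largest difference was that of Upk1b, a uroplakin of the mesothelial marker list, at 1.74 ± 0.28, although it reached only 1.82 CPM in Cre cells.

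The single gene lower with the block was Stab1, a scavenger receptor on the hyaluronan receptor list, which fell by 0.48 on the log2 scale (SE 0.08, adjusted p = 0.0414). These calls depended on the preparations included. With the block, 0 genes were called without preparation 1, 2 or 3, and 115 without preparation 4, the one with the smallest interferon difference. The interferon median, 0.95 with all 4, was 0.89, 1.02, 0.76 and 1.11 without preparations 1, 2, 3 and 4. Without preparation 4 and without the block, 17 genes were called, all higher, 9 of them from the interferon list.

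Hyaluronan genes gave small differences. In the list for hyaluronan synthesis and turnover, 0 of 17 measured genes passed in either fit, with a median of -0.01. Among the 16 receptors and binding proteins 0 passed without the block and Stab1 alone with it. The hyaluronan receptor Cd44 differed by -0.04 ± 0.20, the hyaluronidase Hyal2 by 0.06 ± 0.12 and the hyaluronan-degrading Cemip by -0.43 ± 0.86. Matrix and myofibroblast genes also did not pass. Col1a1 differed by -0.08 ± 0.36, Col3a1 by -0.14 ± 0.50, Fn1 by -0.36 ± 0.46, Postn by -0.32 ± 0.62 and Acta2 by -0.08 ± 0.23. Fibrillar collagen genes as a list had a median of -0.11, which camera called lower only with the block (adjusted p = 0.0016, and 0.81 with an estimated correlation), as it did the integrin list (adjusted p = 0.0374, and 0.81). Across 15259 genes the Cre effect in the blocked fit had a Spearman rho of -0.422 with transcript length. Camera was not run with that trend removed, so its share in the list calls of this comparison was not tested.

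Camera called the glycolysis list (median 0.11, adjusted p = 0.00271, and 0.566 with an estimated correlation) and the mesothelial markers (median 0.32 over 9 genes, adjusted p = 0.00677, and 0.108 with an estimated correlation) higher. In neither list did a gene pass without the block over all genes, and Upk1b alone did with it. The glycolysis call was lost without GFP replicate 1 (median 0.04) or Cre replicate 3 (0.05), and the mesothelial call without GFP replicate 4 (0.56), Cre replicate 2 (0.11) or all of preparation 4 (0.15). Within preparations the glycolysis medians were 0.11, 0.06, 0.12 and 0.05, and the mesothelial medians 0.08, 0.21, 0.17 and 0.02. With the block camera called both higher (adjusted p = 0.00557 and 0.00707, and 0.81 and 0.188 with an estimated correlation). Macrophage and leukocyte markers had a median of -0.01 over 17 genes, none of which passed.

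**Figure D3:**
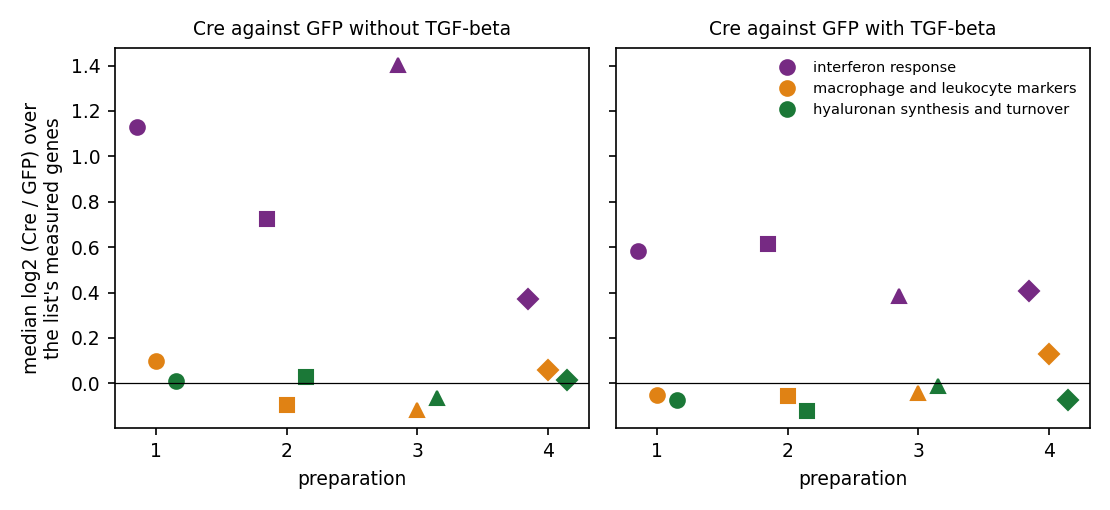
Median log2 ratio of Cre to GFP cells (y axis) in each preparation (x axis) without TGF-beta (left) and with it (right), over the measured genes of the interferon, leukocyte marker and hyaluronan synthesis lists. Interferon medians run from 0.37 to 1.40 without TGF-beta and from 0.39 to 0.61 with it; leukocyte medians run from -0.12 to 0.10 and from -0.06 to 0.13.

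Cre against GFP cells with TGF-beta asked the same of fibroblasts given TGF-beta. Interferon genes again had the higher values in Cre cells, with a median log2 difference of 0.47 and a median above 0 in each preparation (0.58, 0.61, 0.39 and 0.41). Ifit1 was at 20.7 ± 9.33 CPM in GFP cells and 40.8 ± 15.6 in Cre cells (SD, n = 4), a difference of 0.98 ± 0.33 that did not pass the test, and Isg15 differed by 0.83 ± 0.39. Camera called the list higher (adjusted p = 1.19e-13, and 0.536 with an estimated correlation). The median was 0.11 without replicate 4 of the Cre cells with TGF-beta and 0.93 without replicate 4 of the GFP cells with TGF-beta. None of its 42 genes passed over all genes in either fit, while adjusted over the list alone 0 passed without the block and 18 with it.

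EdgeR's quasi-likelihood test called 0 genes without the block, with 268 at an unadjusted p under 0.05 (2039 with the block, where 764 would be expected by chance), and DESeq2 called 0. With the block edgeR called 10 genes, all higher and each in 4 of 4 preparations. They were the nuclear long noncoding RNA Malat1 (1.10 ± 0.12, log2 ± SE, adjusted p = 0.00267), the nucleolar protein gene Esf1 (1.16 ± 0.15), the chaperone Hsp90aa1 (0.81 ± 0.13), the guanylate-binding protein Gbp7 (1.15 ± 0.19), and Luc7l3, Dnajc2, Mphosph8, Ppig, Sltm and Cir1 (0.51 to 0.82). These 10 fall outside the naming rule for the unblocked test and were chosen after their values were seen. Leaving out preparation 1, 2, 3 or 4 changed the count to 9, 0, 3 and 231. After each library's trend on GC content and transcript length was removed, the blocked test called 42.

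No hyaluronan gene passed in either fit. Among 17 genes of hyaluronan synthesis and turnover the median was -0.07, with Gfpt2, of the hexosamine pathway that supplies the sugar precursor, at -0.22 ± 0.14. Cd44 differed by -0.12 ± 0.20, Stab1 by -0.34 ± 0.21, Col1a1 by -0.18 ± 0.36, Col3a1 by -0.21 ± 0.50, Fn1 by -0.32 ± 0.46 and Acta2 by -0.03 ± 0.22. Camera called the fibrillar collagen list lower (median -0.15, adjusted p = 0.0189, and 0.944 with an estimated correlation) and the proteoglycan list lower (median -0.11, adjusted p = 0.0208, and 0.934). Both calls were lost without replicate 1, 2 or 3 of the GFP cells with TGF-beta. Without replicate 4 of the Cre cells with TGF-beta the collagen list turned higher (median 0.07) and the proteoglycan median was -0.02, but leaving out 1 library breaks up its preparation. Within preparations the collagen medians were -0.12, -0.19, -0.11 and -0.30, and the proteoglycan medians were also below 0 in 4 of 4. With the block camera called the collagen list lower (adjusted p = 1.57e-05, and 0.647 with an estimated correlation). The Cre effect with TGF-beta had a Spearman rho of -0.312 with transcript length in the blocked fit, and camera was not run with that trend removed. The 5 measured cardiomyocyte markers, at a median of 0.54, were called higher (adjusted p = 0.0042, and 0.124 with an estimated correlation) with none passing alone. Their median was 0.25 without replicate 4 of the Cre cells with TGF-beta and 0.80 without replicate 1. Mybpc3 was at 0.177 ± 0.0468 CPM in Cre cells with TGF-beta.

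Across the 15285 genes, the Cre effects without and with TGF-beta correlated at r = 0.218 (rho = 0.336); genes are not independent replicates, so no p is given. The value depended on single libraries. It was -0.03 without replicate 4 of the Cre cells, -0.01 without replicate 4 of the Cre cells with TGF-beta, 0.0783 without replicate 2 of the GFP cells and 0.106 without all of preparation 4, but 0.272 without replicate 4 of the GFP cells. Of the 25 and 10 genes called higher with the block, 0 were shared. Independent lists of these sizes would share 0.016, so this overlap cannot show whether the effects differ between the media.

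TGF-beta against no TGF-beta in GFP cells asked what the growth factor did in cells with the control virus. Whether the cells without TGF-beta received basic fibroblast growth factor is not stated. A share of that factor in the differences with TGF-beta, here and in Cre cells, therefore cannot be told apart. Of 30 contractile genes 19 rose, of 28 fibroblast identity genes 19 fell and of 30 inflammatory genes 16 fell, and camera called the 3 lists (adjusted p = 0.108 for each with an estimated correlation). Acta2, the smooth muscle actin of myofibroblasts, went from 328 ± 63.4 to 2245 ± 576 CPM (SD, n = 4). The pro-inflammatory pentraxin Ptx3, which binds the hyaluronan matrix, went from 163 ± 19.3 to 12.8 ± 4.12 CPM.

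EdgeR's quasi-likelihood test called 2105 genes higher and 2340 lower, of which 643 and 1367 changed at least 2 fold. With the block 3451 were higher and 4047 lower. Among the genes with the largest rises were the hormone gene Fgf21 (0.114 to 11.8 CPM), the arginase Arg1 (0.486 to 26.3 CPM), Wnt1 (0.018 to 2.02 CPM), Lhx4, Lelp1 and Alpk2. The fitted folds of such genes depend on the prior count, as they were near 0 in GFP cells. The largest falls were those of the ferritin receptor Scara5 (9.54 to 0.0585 CPM), Fmo2, Aldh3a1, the chemokine Cxcl5 (13.2 to 0.233 CPM), Abi3bp and Ly6c1.

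Among 30 contractile and myofibroblast genes, 19 rose, 0 fell and 11 did not pass (20 rose adjusted over the list alone), and with the block 24 rose and 2 fell. Tpm1 rose by 2.37 ± 0.11 (log2 ± SE), Tagln by 2.87 ± 0.17, the calponin Cnn1 by 5.08 ± 0.41 and Meox1 by 3.63 ± 0.30. Camera called the list higher (adjusted p = 2.31e-17, and 0.108 with an estimated correlation). Of 40 TGF-beta target and feedback genes 17 rose and 6 fell (21 and 8 adjusted over the list alone, 26 and 10 with the block), with the oxidase Nox4 at 2.61 ± 0.24, Ltbp2 at 2.46 ± 0.21 and Ccn2 at 1.05 ± 0.22, while Tgfbi fell by 3.55 on the log2 scale (SE 0.34). The camera adjusted p was 9.97e-05, and 0.108 with an estimated correlation.

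Fibrillar collagen and matrix genes went both ways, and camera did not call the list (adjusted p = 0.0718). Of 37 genes 12 rose and 5 fell, and 19 rose and 8 fell with the block; adjusted over the list alone 14 rose and 5 fell without it. Tnc rose by 3.78 ± 0.44 and Cthrc1 by 2.83 ± 0.27, while Col6a1 fell by 3.31 on the log2 scale (SE 0.52), Postn by 2.15 (SE 0.64, adjusted p = 0.0205) and Col3a1 by 1.51 (SE 0.51, adjusted p = 0.0369). The Col3a1 call was lost without replicate 4 of the GFP cells with TGF-beta (-1.23, adjusted p = 0.0866). Col1a1, at 0.85 ± 0.36, did not pass without the block (adjusted p = 0.0893) and rose with it (adjusted p = 3.74e-07). Fn1 did not pass in either fit (0.18 ± 0.46).

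Of 17 genes for hyaluronan synthesis and turnover 1 rose, 5 fell and 11 did not pass without the block, and 3 rose and 9 fell with it (1 and 5, and 3 and 9, adjusted over the list alone). Hexa, a lysosomal hexosaminidase subunit, fell by 0.76 on the log2 scale (SE 0.12), Gfpt2 by 0.88 (SE 0.15) and the cell-surface hyaluronidase Cemip2 by 0.98 (SE 0.21), while Pgm3 rose by 0.56 ± 0.14. Has2 itself differed by -0.16 ± 0.26 (adjusted p = 0.703). Cemip did not pass without the block (-0.80 ± 0.86) and was called lower with it (-1.10, adjusted p = 0.0118). Of 16 receptors and binding proteins 3 rose, 5 fell and 8 did not pass (3 and 6 adjusted over the list alone), and 3 rose and 9 fell with the block. Cd44 rose by 0.84 ± 0.20, and Ptx3 fell by 3.68 (SE 0.23), Layn by 1.17 (SE 0.11) and Stab1 by 1.16 (SE 0.21). Camera called neither list. Proteoglycan genes split, with 8 of 41 higher, among them Chst11 (2.43 ± 0.21), and 8 lower, among them Prelp (-5.09 ± 0.65), and 10 each way with the block. Of 32 matrix proteases and inhibitors 7 rose and 16 fell (10 and 17 with the block), with Mmp3 at -3.52 ± 0.21 and Htra1 at 1.10 ± 0.11. Camera called the protease list lower only with the block (adjusted p = 0.00122, and 0.647 with an estimated correlation), as it did in Cre cells (adjusted p = 0.000488, and 0.647).

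Fibroblast identity genes had the lowest list median. Of 28 measured, 19 fell, 1 rose and 8 did not pass (21 and 1 adjusted over the list alone, 22 and 1 with the block), at a median of -2.09. Among those that fell were Scara5 (-7.69 ± 0.79, log2 ± SE), Ly6c1 (-5.66 ± 0.26), Cd34 (-4.95 ± 0.47) and S100a4 (-2.36 ± 0.14). The camera adjusted p was 4.55e-16, and 0.108 with an estimated correlation (0.00664 with the block). Of 30 inflammatory genes 16 fell and 4 rose (17 and 4 adjusted over the list alone, 22 and 4 with the block), with the alarmin Il33 at -5.17 ± 0.43, complement C3 at -2.99 ± 0.32 and the cytokine Lif, which rose, at 3.13 ± 0.32. The camera adjusted p was 0.000642, and 0.108 with an estimated correlation. Of 42 interferon genes 26 fell and 0 rose (29 and 0 adjusted over the list alone, 38 and 1 with the block), at a median of -1.26, with Gbp2 at -1.94 ± 0.16 and Ifi27l2a at -3.91 ± 0.42. The camera adjusted p was 9.82e-12, and 0.567 with an estimated correlation.

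Leukocyte markers moved with these groups. Of 17 macrophage and leukocyte markers 3 fell (Mrc1, Adgre1 and Cd68) at a list median of -1.01, and all 17 fell with the block. Camera called the list lower (adjusted p = 0.0084, and 0.934 with an estimated correlation). That call was lost without replicate 4 of the GFP cells (median -0.48), where Adgre1 and Cd68 also no longer passed. Leaving out 1 library breaks up its preparation, and within preparations the marker medians were -0.98, -0.93, -0.96 and -0.9995. With the block camera called the markers lower (adjusted p = 2.92e-09, and 0.188 with an estimated correlation). Of 16 endothelial markers 6 fell, among them Aqp1 (-3.64 ± 0.30) and Tek (-2.23 ± 0.25), and 11 fell with the block (camera adjusted p = 0.00255, and 0.536 with an estimated correlation). Csf1r, a macrophage receptor, was at 69.2 CPM in GFP cells and 39.7 with TGF-beta.

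In the unfolded protein and integrated stress response list 7 of 29 genes rose, 14 with the block, and 0 fell. The 4 named members, Phgdh (1.75 ± 0.18), Asns (1.31 ± 0.14), Mthfd2 (1.65 ± 0.19) and Shmt2 (1.22 ± 0.15), act in serine, asparagine and one-carbon metabolism and not in protein folding. The camera adjusted p was 0.000562, and 0.789 with an estimated correlation. The list median of 0.27 was 0.04 without replicate 4 of the GFP cells with TGF-beta and 0.54 without GFP replicate 4. Leaving out 1 library breaks up its preparation, and within preparations the medians were 0.30, 0.21, 0.15 and 0.38. In the blocked fit the camera adjusted p was 0.000636, and 0.464 with an estimated correlation. Of 15 mitochondrially encoded transcripts 5 rose and 0 fell, and 10 rose with the block, at a median of 0.48 (camera adjusted p = 0.00837, and 0.789 with an estimated correlation). By preparation the medians were 0.67, 0.71, 0.75 and -0.01, and without preparation 4 the median was 0.73. Their share of counts was 0.593 ± 0.192% in GFP cells and 0.788 ± 0.0745% with TGF-beta (SD, n = 4).

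TGF-beta in Cre cells asked the same where the Cre virus had been given. EdgeR's quasi-likelihood test called 2134 genes higher and 2495 lower, 674 and 1405 of them at least 2 fold, and 3856 and 4174 with the block. The response was close in size to that in GFP cells. Acta2 rose by 2.83 ± 0.24 (log2 ± SE), Tagln by 2.94 ± 0.17, Nox4 by 2.84 ± 0.23, the endothelin gene Edn1 by 2.21 ± 0.19 and Cd44 by 0.75 ± 0.20. Genes that fell included Scara5 (-8.08 ± 0.81), Il33 (-5.23 ± 0.43), Mmp3 (-3.61 ± 0.21), Ptx3 (-3.85 ± 0.23) and Postn (-1.90 ± 0.64). Col3a1 fell by 1.57 (SE 0.51), a call lost without replicate 4 of the Cre cells with TGF-beta (-1.27, adjusted p = 0.0573), and Col1a1 passed only with the block (0.73, adjusted p = 1.40e-06). The largest rises were those of Fgf21 (0.0638 to 12.1 CPM), Lhx4, Cdh6 (0.782 to 35.1 CPM), Lef1, Chst5 and Add2, and the largest falls those of Scara5, Ackr4, Chst8, Ppp1r3c (65.2 to 0.978 CPM), Gpr182 and Cxcl5.

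By list, 20 of 30 contractile genes rose and 0 fell (24 and 3 with the block), 18 of 40 TGF-beta targets rose and 5 fell (23 and 10), and 20 of 28 fibroblast identity genes fell and 1 rose (22 and 1). Of 30 inflammatory genes 17 fell and 4 rose (23 and 4 with the block), and of 42 interferon genes 32 fell (36 adjusted over the list alone, 39 with the block) at a median of -1.65. Camera called all 5 lists, with adjusted p between 0.0946 and 0.475 with an estimated correlation. Of 17 genes for hyaluronan synthesis 1 rose and 5 fell (3 and 8 with the block). Of 16 receptors and binding proteins 3 rose and 6 fell (3 and 7), a list camera called lower (adjusted p = 0.0493) without the block but not with it (adjusted p = 0.149), nor with an estimated correlation (adjusted p = 0.2). That call was also lost without replicate 3 (median -0.60) or 4 (-0.55) of the Cre cells, replicate 4 of the Cre cells with TGF-beta (-0.53), or all of preparation 4 (-0.42), and with RLE size factors (adjusted p = 0.0524). Leukocyte markers had a median of -0.92 with 3 of 17 lower, and 16 with the block. Camera called them lower (adjusted p = 0.0169, and 0.934 with an estimated correlation), but not without replicate 4 of the Cre cells (median -0.45) or replicate 1 of the Cre cells with TGF-beta (-0.75). Within preparations the marker medians were -1.16, -0.81, -1.01 and -0.87. In the blocked fit camera called the markers lower (adjusted p = 1.55e-08, and 0.188 with an estimated correlation). Of 15 mitochondrial transcripts 11 rose, and 12 with the block.

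**Figure D4:**
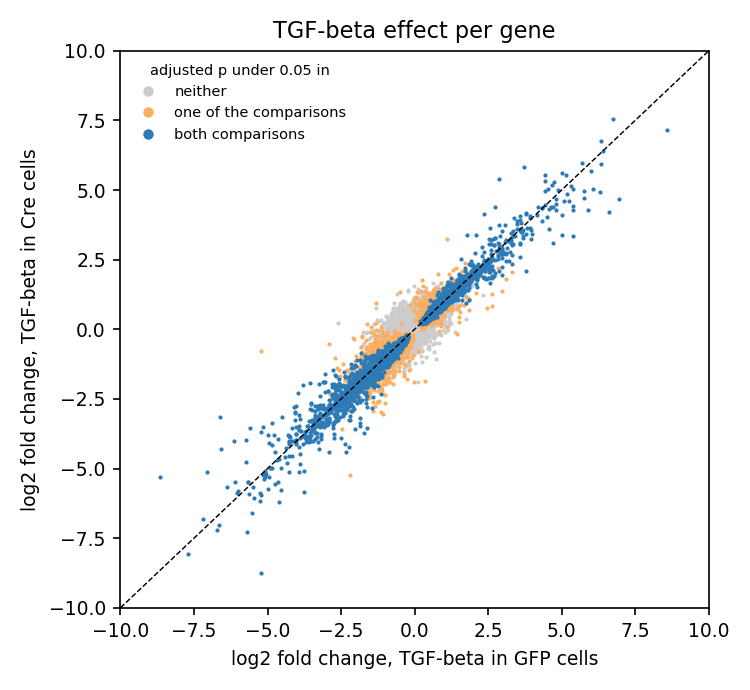
Log2 fold change with TGF-beta in GFP cells (x axis) and in Cre cells (y axis) for each of the 15285 tested genes; colours show in how many of these comparisons the gene's adjusted p was under 0.05, and the dashed line marks equal change. Points lie along the line (r = 0.943), with 1779 genes called higher and 2045 called lower in both.

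**Figure D5:**
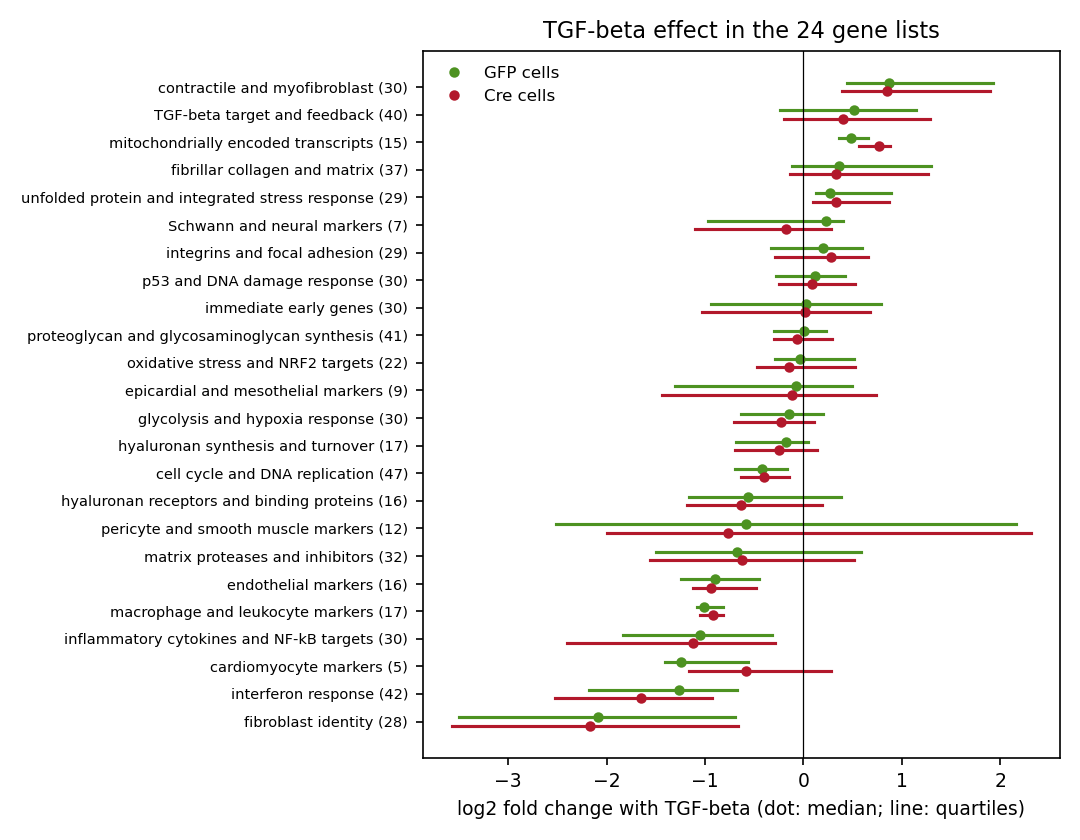
Log2 fold change with TGF-beta (x axis) in the 24 gene lists (y axis, with the number of measured genes); dots give the median and lines the quartiles over genes, in GFP and in Cre cells. Contractile genes have the highest medians (0.87 and 0.85) and fibroblast identity genes the lowest (-2.09 and -2.17).

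The difference of the TGF-beta responses tested whether the Cre virus altered the effect of TGF-beta. No gene passed edgeR's quasi-likelihood test, with 0 called without the block (90 at an unadjusted p under 0.05), 0 with the block (501) and 0 by DESeq2. Acta2 differed between the responses by 0.05 ± 0.32 (log2 ± SE), Col1a1 by -0.10 ± 0.50, Has2 by 0.32 ± 0.37 and Cd44 by -0.09 ± 0.28. Of the genes called higher with TGF-beta, 1779 were shared between GFP and Cre cells where independent lists would share 294. Of those called lower 2045 were shared where independent lists would share 382, and 0 genes were called in opposite directions (3 with the block). The effects correlated across genes at r = 0.943 (rho = 0.891).

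Among lists, camera called the interferon genes lower in this difference (median -0.35, adjusted p = 2.21e-11, and 0.583 with an estimated correlation). None of the 42 passed alone, Gbp2 differed by -0.69 ± 0.23, and the per-preparation medians were -0.47, -0.16, -0.83 and -0.02. That call was lost without replicate 4 of the GFP cells with TGF-beta, where the median was 0.04, and the median was -0.70 without replicate 4 of the Cre cells with TGF-beta. Camera also called the glycolysis list lower (median -0.13, adjusted p = 0.000157, and 0.475) and the mitochondrial transcripts higher (median 0.19, adjusted p = 0.00677, and 0.789), and 0 of their 30 and 15 genes passed. The mitochondrial call was lost on leaving out any of GFP replicate 4 (median 0.03), Cre replicates 2 (0.13) or 3 (0.11), and replicates 1 (0.15) or 3 (0.17) of the Cre cells with TGF-beta. Within preparations the mitochondrial medians were 0.19, 0.03, 0.21 and 0.25.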

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

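The patterns weighed here were picked once the comparisons had been seen, and the Has2 tests and the GC and length correction were chosen only then; what each explanation of the interferon genes and of the 10 genes would give was written down before its test was run, but for Has2 after.

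Single libraries stood apart from the other 3 of their group in 5 of 60 group checks, where chance gives about 1 in 20, and all 5 belonged to preparation 4. Col1a1 was at 8661 CPM in replicate 4 of the GFP cells with TGF-beta, against 19368 to 21328 in the others, and at 7320 CPM in replicate 4 of the Cre cells with TGF-beta, against 17069 to 18726. In that last library Fn1 was at 3161 CPM, against 12887 to 14231. The 10 most abundant genes took 7.34% of counts in GFP replicate 4, against 11.0% to 11.5%, and 6.88% in replicate 4 of the Cre cells with TGF-beta, against 10.5% to 11.0%. Leukocyte markers were more abundant in the same preparation, with Ptprc at a mean of 15.9 CPM and C1qb at 182, against 3.72 to 5.36 and 55.5 to 69.3 CPM in the others.

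The effect of TGF-beta differed between Cre and GFP cells for 3 gene lists by camera at the preset correlation, with a median of -0.35 for interferon genes, -0.13 for glycolysis genes and 0.19 for mitochondrially encoded transcripts. None was called with an estimated correlation (adjusted p = 0.583, 0.475 and 0.789). The interferon call was lost without replicate 4 of the GFP cells with TGF-beta (median 0.04), and the mitochondrial call on leaving out any of 5 single libraries.

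Interferon genes were higher in Cre than in GFP cells without TGF-beta. Leukocytes in the Cre cultures would raise their markers by about as much, but the highest of the 4 per-preparation medians of the 17 leukocyte markers was 0.0995, against an interferon median of 0.95 in the fit with the block (0.914 with the GC and length trends removed, where 23 of the 26 calls were kept among 34). A single preparation is also argued against, since the lowest median with 1 preparation left out was 0.764. Loss of Has2 exon 2 and the Cre virus itself cannot be told apart, because no cells known to lack a floxed allele were set beside the others, and with TGF-beta the interferon median was 0.487. The genotype field reads wild type, and if no floxed allele was present, exon 2 cannot have been deleted and its loss cannot be the cause, so this and differences between the virus stocks stay open.

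With TGF-beta, 10 genes were higher in Cre cells in the fit with the block. Across 15259 genes the Cre effect with TGF-beta had a Spearman rho of -0.312 with transcript length (-0.422 without TGF-beta) and -0.250 with GC content, but by preparation the GC values were -0.145, -0.313, -0.346 and 0.0984. After both trends were removed, the median log2 difference of the 10 genes was 0.712, against 0.81 before, with a median SE of 0.109, and 9 of the 10 were still called, so these trends do not account for the whole. The lowest median with 1 preparation left out was 0.747. That median cannot decide whether 1 preparation accounts for the pattern, because the 10 genes were chosen by passing over all 4 preparations. Without preparation 1, 2, 3 or 4 the blocked test still called 7, 0, 2 and 10 of them. What raised these genes stays open, and RNA quality was not analysed here.

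Has2 counts differed little between the viruses. Loss of the whole transcript in most cells would give a log2 difference of -1 or below. The lower 95% bound of the paired difference averaged over both media was -0.409, and without TGF-beta alone it was -0.645. Loss of the exon 2 reads alone in all cells would give -0.23. No recombination would give 0, and is the only outcome if the cells were wild type as the genotype field reads. These last outcomes cannot be told apart, because the average of -0.178 has an upper bound of 0.0533 and both values lie in the interval. Reads over exon 2, which were not used here, would separate them. Loss in only part of the cells was not weighed.

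Other groupings of the same libraries were counted for each comparison. For TGF-beta in GFP cells the real grouping called 4445 genes and the highest other of the 35 splits 1, and in Cre cells 4629 and 0, so that 1 of 35 splits reached the count in each. By that count a chance split can be excluded, but it treats the 8 libraries as exchangeable although same-numbered ones share a preparation. For Cre against GFP the real count was 0, so 35 of 35 splits reached it in both media. The highest other split called 48 genes without TGF-beta and 93 with it, and each of these kept whole preparations together, which points to the preparations as a structure of the samples. For the difference of the responses 100 of 100 drawn groupings reached the real count of 0, and the highest other was 0. With the block only 8 splits part every pair, too few for a share under 0.05. There the real split called 26, 10, 7498 and 8030 genes in the first 4 comparisons, the highest other called 0 in each, and 1 of 8 splits reached the real count.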

How the results depend on the processing

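Camera with both an estimated correlation and the block, the GC and length correction, and the unblocked fit without all of preparation 4 were chosen after seeing the data. With the replicate block, Cre against GFP gave 26 genes without TGF-beta and 10 with it, and TGF-beta gave 7498 in GFP and 8030 in Cre cells, in place of 0, 0, 4445 and 4629, of which 4444 and 4629 were shared; the cause is the smaller spread left between libraries. The block also added the collagen and integrin lists without TGF-beta and the protease list for TGF-beta in both cell groups, and ended the receptor list in Cre cells. DESeq2 gave 3 genes for Cre against GFP without TGF-beta. The blocked count with TGF-beta was 42 with the GC and length trend removed. A required fold of 1.5 left 1481 and 1528 TGF-beta genes, by construction. Leaving out 1 library or preparation gave 0 to 115 genes for Cre against GFP without TGF-beta, 0 to 231 with it, 3364 to 8033 for TGF-beta in GFP cells, 3472 to 8566 in Cre cells and 0 for their difference. The highest counts came with the block and without preparation 4 (17 without the block, in the first comparison). The Has2 difference ranged from -0.43 to -0.22 without TGF-beta and from -0.30 to 0.12 with it, and was not called in any fit.

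The correlation of the Cre effects, 0.218, was 0.0343 with no filter on low counts, 0.430 with a strict filter and 0.336 as Spearman's rho. Without 1 library it ranged from -0.0251 (without Cre replicate 4) to 0.316, and was -0.0118 without replicate 4 of the Cre cells with TGF-beta. In the blocked fit without 1 preparation it ranged from 0.114 (without preparation 4) to 0.234. The cause was not tested. The correlation of the TGF-beta effects, 0.943, was 0.455 with no filter on low counts, 0.975 with a strict one and 0.905 to 0.942 without 1 library. Of 29 list calls, 0 held with an estimated correlation, and 3 with it and the block. Fry called 21, of which 16 were shared, RLE size factors 28 and the block 32. Without 1 library 29 to 46 lists were called, with 46 without replicate 4 of the GFP cells with TGF-beta and 44 without that of the Cre cells with TGF-beta. Without replicate 4 of the Cre cells with TGF-beta, camera gave the proteoglycan list the other direction in the Cre comparison with TGF-beta, though it was not called (adjusted p = 0.497) and its median stayed below 0 (-0.0239), and the fibrillar collagen list turned, its median ranging from -0.352 (without replicate 4 of the GFP cells with TGF-beta) to 0.0699; dropping 1 library of a preparation unbalances the unblocked groups.

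For 552 combinations of named gene and comparison, 208 were called. The strict filter gave the same call for all 447 it kept and RLE factors for all 552. DESeq2 added 7, sex as a covariate 5 and the block 21, while no filter lost 14 and a fold of 1.5 lost 53. With only the libraries compared 2 calls were added and 4 lost. No named gene changed direction while called, and 6 of the 4206 values under alternatives other than leaving out libraries changed sign, all uncalled. Of the lowest and highest values without 1 library or 1 preparation, 15 gained a call and 15 lost one. These values include the blocked fits without 1 preparation, so a gained call can also come from the block. Depth limited Has3 (0 to 10 counts), which was not tested, and genes under about 1 CPM.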

Other observations

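Lists not described so far are given for TGF-beta in GFP cells, gene by gene with edgeR's quasi-likelihood test without the block. Of the focal adhesion genes, 9 of 29 rose and 4 fell (10 and 4 adjusted over the list alone, 14 and 8 with the block). The fibronectin receptor subunit Itga5 rose by 2.04 ± 0.16 (log2 ± SE), the kinases Ilk by 0.78 ± 0.08 and Ptk2 by 1.03 ± 0.12, and caveolin Cav1 fell by 2.17 (SE 0.22). In the immediate early list 9 of 30 genes rose and 9 fell, and 12 each way with the block. Among them Ier3 rose by 1.70 ± 0.17, and Spry2 fell by 1.56 (SE 0.19), Spry4 by 1.30 (SE 0.17) and the transcription factor Etv5 by 1.30 (SE 0.16). The angiogenic factor Vegfa rose by 1.78 ± 0.12, while 9 of the 30 genes on the glycolysis and hypoxia list fell, among them Pfkl (-0.59 ± 0.09), Egln3 (-1.42 ± 0.22) and Adm (-2.71 ± 0.35), and 4 rose (15 and 6 with the block).

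Among p53 and DNA damage genes 8 of 30 rose and 4 fell (9 and 9 with the block), with Plk2 at 1.92 ± 0.15, Gdf15 at 1.57 ± 0.26 and Sesn1 at -1.40 ± 0.20. Of 22 oxidative stress genes 5 rose, with Txnrd1 at 1.12 ± 0.16, and 5 fell, with Gstm1 at -2.72 ± 0.22, and 8 went each way with the block. Of 47 cell cycle genes 3 fell, Ccnd1 (-1.18 ± 0.24), Bub1b (-1.01 ± 0.27) and Tk1 (-1.14 ± 0.39), while 18 fell and 3 rose with the block. The list median was -1.06, -0.84 and -0.76 in preparations 1 to 3 and 0.34 in preparation 4. Of 12 pericyte and smooth muscle markers 3 rose, Cnn1, Cspg4 (2.62 ± 0.30) and Actg2 (2.96 ± 0.35), and 5 fell, with Steap4 at -4.20 ± 0.50 (5 and 6 with the block). Of 5 cardiomyocyte markers 3 fell (4 with the block), of 9 mesothelial markers 1 rose and 2 fell (2 and 3), and of 7 Schwann and neural markers 1 fell, Cdh19 at -1.65 ± 0.47 (3 with the block). Camera called none of these 10 lists.

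No gene passed a test of whether any of the first 4 effects differed between the 2 male and 2 female preparations in the fit with the block. By edgeR's quasi-likelihood test 0 were called in each, with 263, 518, 614 and 955 genes at an unadjusted p under 0.05.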
